A study of Homo sapiens with 12 samples.

How the data were processed

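RNA was measured in 12 libraries of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen and is widely used because it takes up foreign DNA well. Per the labels, cells received 500 ng of a plasmid for miR-211 or a control plasmid, or 1 nM of a Dicer-substrate siRNA against U1 small nuclear RNA or a scrambled oligo, and total RNA was taken 24 h after transfection. Each of the 4 groups has 3 libraries. The labels state paired-end reads of 126 nt on an Illumina HiSeq2500. How RNA was selected for the libraries, and whether the kit kept strand, is not given in the sources used here.

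The deposited values are read counts per gene. The submitters' processing notes name STAR 2.7.2a, and the layout of the deposited count tables is that of STAR's per-gene output, with an unstranded column, 2 strand columns and 4 summary lines for pairs that were unmapped, mapped to several places, fell outside genes or were ambiguous. The notes also name GRCh37 and hg19. The gene identifiers in the tables point to another build: all 58735 are those of GENCODE release 29, an annotation made on GRCh38. Which build the reads were aligned to was therefore left open, and every coordinate printed here is from GENCODE 29 on GRCh38 and was not taken from the deposited files. The counts carry no normalization by the authors.

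The 2 strand columns differed by less than the limit of 1.5 times in total (0.990 to 1.10), so the unstranded column was used. Counted without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and a pair over overlapping genes is counted for none of them. A gene count does not measure splicing: intron retention, exon skipping and splice site choice are not visible in these files. The summary lines were kept out of library sizes and tests. STAR counts genes over their exons, so the pairs called outside genes here lay outside annotated exons, in introns or between genes. Pairs outside genes made up 14.5% to 44.5% of uniquely mapped pairs, and unmapped pairs 7.92% to 14.2% of all pairs.

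Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr and the quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, on the 6 libraries of each comparison. The difference between both effects was tested as an interaction over all 12 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation. The design, the alternatives, 27 gene lists and the rule for naming genes were fixed before the data were examined. The rule named genes past the threshold. Because fewer than 10 passed, it took the 5 highest and 5 lowest protein-coding genes by signed p with a mean CPM of at least 1, given as values that did not pass. A gene that the rule picked for U1 siRNA is not reported here. The target genes, the U1 snRNP proteins and the microRNA processing genes DROSHA, DGCR8, DICER1 and XPO5 were always given. Genes outside the rule are said to be so where they are named.

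The U1 snRNA target check was fixed as the summed CPM of 15 annotated U1 genes chosen by symbol. A second set, the 14 annotated genes that hold the whole 27 nt target of the siRNA sequence printed in the labels, was defined only after the data were seen and is given beside the first. Single values of 3 against 3 libraries were compared by 2-sided exact permutation tests, in which the smallest possible p is 0.1. Ratios of summed counts have exact 95% intervals, which cover counting error only. From GENCODE 29 came gene spans, 3 prime UTRs (19145 protein-coding genes), host genes of intronic microRNAs (728) and miR-211 seed sites.

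Whether replicate numbers pair the samples was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. For miR-211 and plasmid control these were 0.248, 0.305 and 0.239, all above 0.1, so the numbers were taken to pair the libraries. The labels do not say what a number stands for, nor that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. All pairs of replicates differed by more than counting noise (chi-square per degree of freedom 2.15 to 7.25), so none was taken as the same library sequenced again. This cannot tell whether replicates were separate libraries of the same RNA.

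The test was run on simulated counts with the means, depths and dispersions of the real libraries and 200 changed genes. Genes were drawn independently and libraries without pairing, and many changed genes ease the adjusted threshold. For miR-211 (12685 genes) it recovered 48.7% of genes changed by 1.5-fold, 78.0% at 2-fold and 92.7% at 3-fold. For U1 siRNA (12413 genes) it recovered 38.0%, 68.5% and 84.8%. At 1.5-fold, 9.60% and 10.5% of the calls were false, above the nominal 5%. Alternatives covered DESeq2 1.42.0, limma-voom, other scaling and filters, the strand columns, a replicate block, a fit on all 12 libraries and each library left out. The share of pairs outside genes as a covariate and the second U1 set were added after seeing the data.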

Results

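Gene expression was measured by RNA sequencing in HEK293T cells, a human embryonic kidney line, 24 h after transfection. The series title names mRNA splicing and intronic microRNAs, microRNAs encoded inside introns of other genes. Cells given a plasmid for miR-211 (3 libraries) were compared with cells given a control plasmid (3 libraries), and cells given an siRNA against U1 small nuclear RNA, the RNA of the particle that recognises 5 prime splice sites, were compared with cells given a scrambled oligo (3 libraries each). Counts over all genes totalled 6070116 to 8459646 per library with miR-211, 6226067 to 7484566 with the control plasmid, 4515728 to 6343000 with U1 siRNA and 5903205 to 9290686 with the scrambled oligo. U1 siRNA replicate 2 stood apart: it had the lowest total, 4515728, and the most genes detected, 39294. Of its uniquely mapped pairs, 44.5% lay outside annotated exons, in introns or between genes, against 14.5% to 25.5% in the other 11 libraries.

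MIR211 was the only gene past the threshold with the miR-211 plasmid. This microRNA gene (ENSG00000207702, chromosome 15, 31065032 to 31065141, GRCh38) lies in an intron of TRPM1, which codes for a cation channel of melanocytes and retinal cells. It rose from 0.535 ± 0.674 CPM with the control plasmid to 258.5 ± 15.8 CPM (SD, n = 3 each), a log2 fold change of 8.88 (SE 0.23, edgeR quasi-likelihood test, adjusted p 2.97e-12). Counts were 1646, 1997 and 1976 in the miR-211 libraries and 1, 9 and 1 in the controls, and the ratio of totals was 480 (95% interval 268 to 961). Counts over the hairpin gene do not measure the mature microRNA, and reads from the plasmid and from the chromosomal gene cannot be told apart. TRPM1 itself had 1 to 11 counts per library in these groups and was below the expression filter, with a ratio of totals of 0.884 (0.418 to 1.86).

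**Figure D1:**
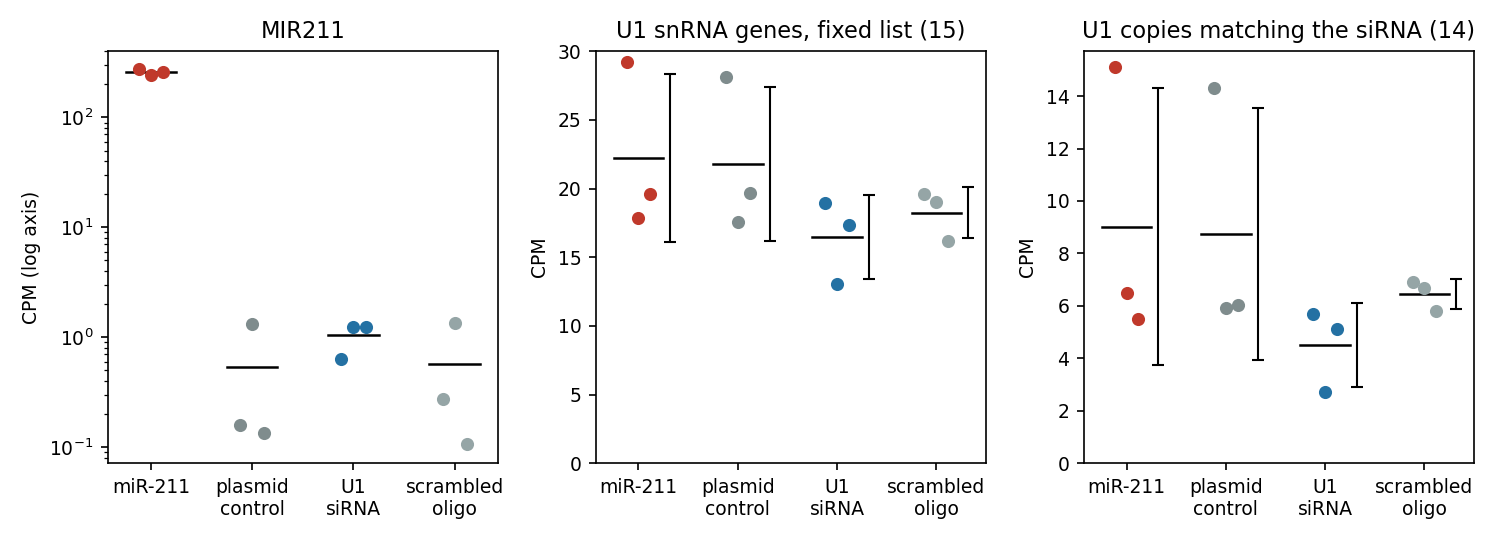
CPM per library of MIR211 (log axis), of the 15 U1 snRNA genes of the list fixed beforehand and of 14 U1 copies matching the siRNA, a set chosen after the data were seen. Points are libraries, horizontal lines group means and bars SD (n = 3), which the MIR211 panel does not have. MIR211 lies between 244 and 273.4 CPM in the miR-211 libraries and at or under 1.33 CPM elsewhere.

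Across the 12685 genes tested, 1 was higher and 0 were lower. At an unadjusted p under 0.05 there were 417 genes, 3.29% of those tested, where chance gives 5%. With the replicate numbers as a block, which the pairing check calls for, there were 943 of 12685, a share above 5%. In 8.67% of genes the 3 libraries of each group did not overlap, where chance gives 10% for libraries that are not paired, and pairing lowers that share. Of 7398 genes with a mean CPM of at least 10, 99.9% had a log2 fold change within 0.5 of 0. DESeq2 and limma-voom also called 1 gene each. On simulated counts of this comparison, 78.0% of genes changed by 2-fold were called and 48.7% of those changed by 1.5-fold. With 200 independent genes changed at once, such shares can lie above those for a few changed genes.

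**Figure D2:**
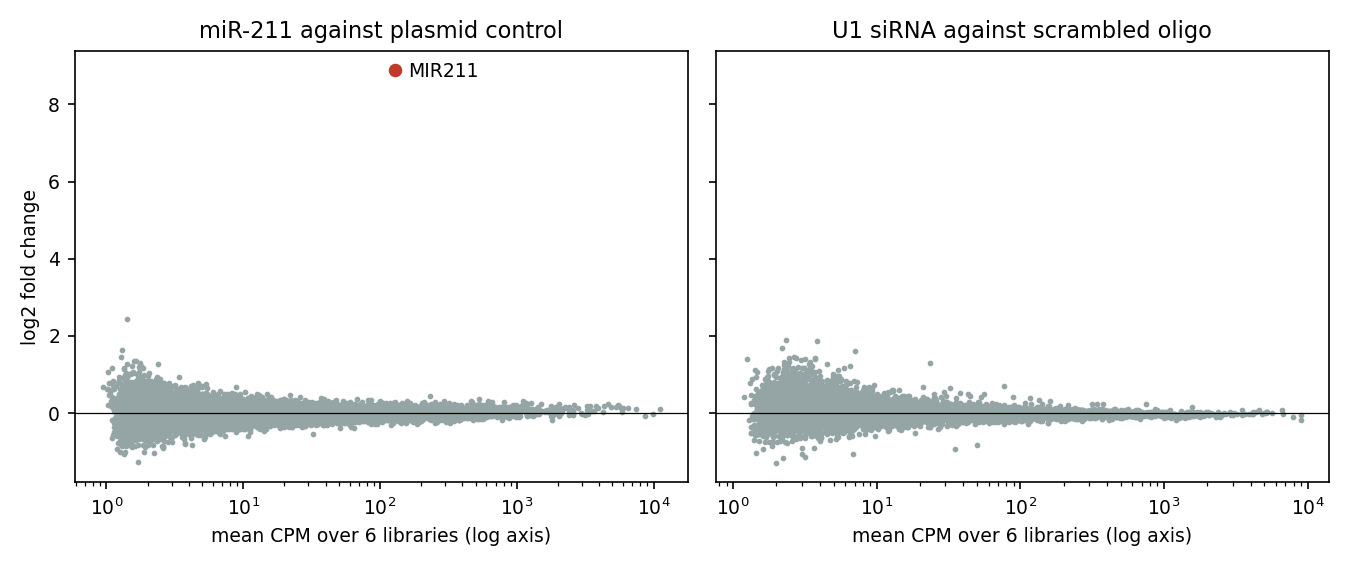
Log2 fold change against mean CPM (log axis) of each tested gene, for miR-211 against plasmid control (12685 genes) and U1 siRNA against scrambled oligo (12413 genes). Red marks the gene with an adjusted p under 0.05, MIR211, and no gene is marked for U1 siRNA.

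None of the protein-coding genes that the naming rule picked passed the test with miR-211 (adjusted p 0.996 for each, edgeR, and 0.467 to 0.613 with the replicate block). The highest by signed p included 2 proteins of the spliceosome's U5 particle. SNRNP200, an RNA helicase, had 509.2 ± 60.7 CPM against 409.1 ± 17.2 (log2 fold change 0.31, SE 0.09). PRPF8, the spliceosome's scaffold protein, had 687.1 ± 97.2 against 548 ± 10.3 CPM (0.33, SE 0.09). The others were EIF6, a ribosome biogenesis factor (0.26), LTB4R, a leukotriene receptor (0.94), and FXYD5, a regulator of ion transport (0.26). The lowest were AIDA (-0.58), ETNK1, an ethanolamine kinase (-0.28), USP42, a ubiquitin protease (-0.44), MAPKAPK5, a protein kinase (-0.39), and ERCC6L2 (-0.31). AIDA had -0.12 and -0.34 in the separate strand columns, ERCC6L2 -0.20 in strand column 4, LTB4R 0.60 in strand column 3 and PRPF8 0.22 without miR-211 replicate 1. The microRNA processing genes had log2 fold changes of 0.13 for DROSHA, 0.06 for DGCR8, -0.05 for DICER1 and 0.09 for XPO5 (SE 0.09, 0.15, 0.09 and 0.08). Without miR-211 replicate 1 DROSHA had 0.06 and XPO5 -0.0003, without plasmid control replicate 1 DICER1 had 0.001, and DGCR8 had -0.15 in strand column 3. The U1 particle's proteins SNRNP70, SNRPA and SNRPC had 0.06, -0.07 and 0.08 (SE 0.15, 0.13 and 0.07), and SNRNP70 had -0.16 in strand column 4 and SNRPA 0.10 in strand column 3.

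Genes described in the literature as targets of miR-211 or its relative miR-204 were not called as a group. Of 47 measured, 17 were higher and the rest lower in value, with a median log2 fold change of -0.04 (camera p 0.0549, adjusted p 0.285, and p 0.0977, adjusted p 0.423 with the replicate block), and 0 members were called, both over all genes and adjusted over the list alone. The median ran from -0.06 without miR-211 replicate 2 to -0.02 without plasmid control replicate 2. Their mean log2 CPM minus that of the other tested genes was lower with miR-211 than in the control of the same number in 3 of 3 pairs. Members at either end of the list, chosen after their values were seen, were SIRT1, a deacetylase, with a log2 fold change of -0.26 (SE 0.12), SNAI1, a transcription factor (-0.85, SE 0.44), ITPR1, a calcium channel (0.42, SE 0.16), and NTRK2, a neurotrophin receptor (1.00, SE 0.61). Genes with an 8mer match to the miR-211 seed in the 3 prime UTR (1084) had a median of -0.01, against 0.01 for other genes (difference -0.01, camera p 0.602, adjusted p 0.753). The other genes included those with 7mer matches only, which can make a difference smaller. The difference ran from -0.03 without miR-211 replicate 1 (adjusted p 0.606) to -0.001 without plasmid control replicate 1 (0.725). Genes with only 7mer matches (2257) differed from the others, the 8mer genes among them, by -0.01 (camera p 0.836, adjusted p 0.836). In the U1 siRNA comparison, without the plasmid, the same 8mer difference was -0.0003 (p 0.770). Among the 56 8mers of the same bases, the seed 8mer ranked 12 from the lowest by this difference, which ran from -0.03 to 0.004. On simulated counts with independent genes, a shift of 0.05 log2 of the 8mer genes passed p under 0.05 in 10 of 10 runs. Correlated genes would make the test less able than that.

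**Figure D3:**
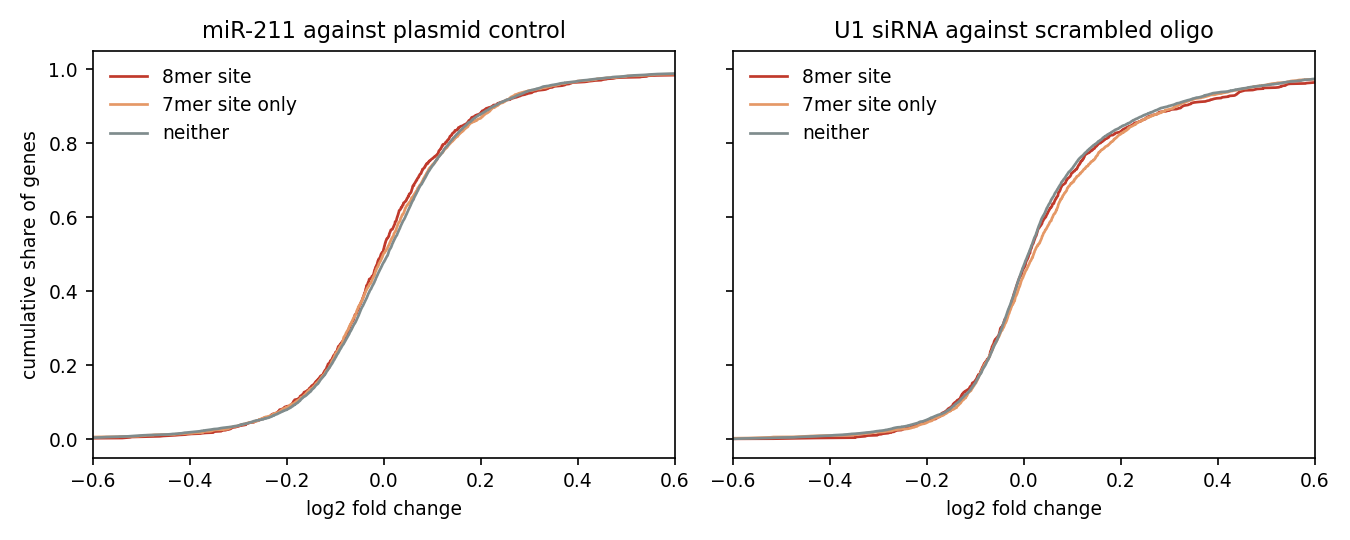
Cumulative share of protein-coding genes by log2 fold change, for genes with an 8mer seed site in the 3 prime UTR, with 7mer sites only, and with neither. The curves lie close together in both comparisons, and the 8mer genes differ from the others by -0.01 at the median with miR-211.

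Ribosomal protein genes were the only list past the threshold with miR-211. They were higher in value in 69 of 83 members, with a median log2 fold change of 0.09 (camera, adjusted p 6.86e-05), and 0 members passed over all genes or adjusted over the list alone. The adjusted p was 0.963 with an estimated correlation, and the call was lost without plasmid control replicate 1 (median 0.03, adjusted p 0.481) or without miR-211 replicate 2 (median 0.04, adjusted p 0.300). Of its members, chosen after their values were seen, RPLP2 had 1391 ± 113.7 CPM against 1167 ± 102.4, and RPS28 had 1221 ± 152.9 against 988.4 ± 113.9. Mitochondrially encoded genes were higher in value in 14 of 16 members (adjusted p 0.109), and they passed without plasmid control replicate 1 (0.0172) or without miR-211 replicate 3 (8.91e-05). Over all 6 libraries their adjusted p was 0.963 with an estimated correlation. Members were higher in value in 7 of 27 for hnRNP proteins, which bind nascent transcripts (adjusted p 0.255). The U4/U6.U5 tri-snRNP list had 14 of 23 members higher (adjusted p 0.553), and adjusted over the list alone it had 2 called, SNRNP200 and PRPF8. Members higher in value numbered 14 of 23 for microRNA biogenesis, 3 of 16 for the U1 snRNP and partners, 10 of 21 for Sm core and assembly, 10 of 18 for the U2 snRNP, 8 of 22 for SR proteins and 11 of 22 for cleavage and polyadenylation. They numbered 11 of 19 for nonsense-mediated decay, 16 of 24 for replication-dependent histones, 13 of 20 for interferon-stimulated genes, 0 of 3 for the inflammatory response, 5 of 15 for immediate early genes and 11 of 21 for p53 targets. They numbered 17 of 30 for the unfolded protein response, 7 of 16 for heat shock, 10 of 22 for cholesterol synthesis, 14 of 36 for mitosis, 15 of 37 for DNA replication and 14 of 24 for hypoxia and glycolysis. Melanocyte genes were higher in 3 of 4, fibroblast markers in 2 of 5 and U1 snRNA genes in 2 of 5. None of these lists passed, their adjusted p lying between 0.259 and 0.929, and blood cell markers, with 2 measured, were not tested. Histones passed without plasmid control replicate 3 and with the share of pairs outside genes as a covariate, and their adjusted p over all 6 libraries was 0.963 with an estimated correlation.

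Host genes of intronic microRNAs (484 measured) had a median log2 fold change of 0.02 with miR-211, against 0.005 for other protein-coding genes (p 0.437, adjusted p 0.728). The difference of 0.02 ran from -0.002 without plasmid control replicate 2 to 0.04 without plasmid control replicate 3, and it was -0.004 with the share of pairs outside genes as a covariate. The longest 10% of protein-coding genes (1096, spans of at least 188.3 kb) had a median of 0.03, against 0.003 (p 0.0195, adjusted p 0.0975). With the replicate numbers as a block, which the pairing check calls for, the difference was 0.03 with an adjusted p of 0.0413, and with an estimated correlation the adjusted p was 0.712. The difference was 0.07 without plasmid control replicate 1 (adjusted p 0.000326) and 0.09 without miR-211 replicate 2 (0.000109), but -0.01 without miR-211 replicate 1 (0.966), 0.01 without plasmid control replicate 2 (0.905) and -0.03 with the share of pairs outside genes as a covariate (0.626), a setting chosen after the data were seen. That share was higher with miR-211 in each of the 3 pairs (24.3% and 21.8%, 16.3% and 14.5%, 22.9% and 16.8%), as was the number of genes detected. The share of unmapped pairs was lower in each (8.87% ± 0.817 against 9.91% ± 0.440, SD, n = 3 each). The exact permutation tests ignored the pairing. They gave p 0.1 for unmapped pairs, the smallest that 3 against 3 allows, and p 0.3 for the share outside genes. Single-exon genes (146) differed by -0.01 (adjusted p 0.728).

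For the target, U1 snRNA, the check fixed beforehand gave no difference beyond the spread between libraries. The 15 listed U1 genes summed to 16.4 ± 3.04 CPM with U1 siRNA and 18.3 ± 1.84 CPM with the scrambled oligo (SD, n = 3 each), a difference of -9.87% (exact permutation p 0.5). Single libraries had 19.0, 13.1 and 17.3 CPM with U1 siRNA and 19.6, 19.0 and 16.2 with the scrambled oligo. The ratio of totals was 0.929 (0.795 to 1.08), an interval for counting error only that leaves out the 30% inhibition stated in the labels, and without U1 siRNA replicate 2 the difference was -0.637%. U1 RNA carries no poly(A) tail, and since the preparation of the libraries is not given, these counts may not measure its level, so that the ratio is no test of the stated inhibition. The siRNA sequence printed in the labels is CCACAAATTATGCAGTCGAGTTTCCCA. Its reverse complement, TGGGAAACTCGACTGCATAATTTGTGG, was found at bases 107 to 133 of RNU1-1 (chromosome 1, 16514122 to 16514285, GRCh38), in the exon of this 164-base gene, and in 13 other annotated copies. Summed over these 14, a set chosen after the data were seen, U1 had 4.51 ± 1.59 CPM against 6.46 ± 0.58, a difference of -30.3% (exact permutation p 0.1, the smallest 3 against 3 allows), resting on 78 and 145 counts. The ratio of totals was 0.727 (0.545 to 0.964), and leaving out a library gave differences from -39.5% without U1 siRNA replicate 1 to -16.3% without U1 siRNA replicate 2. The fixed list held 281 and 409 counts, so most of its counts came from U1 copies without the whole siRNA target. The value thus depends on which copies are summed, and reads that fit several near-identical copies were not counted. In the miR-211 comparison, without the siRNA, the same 14 copies had a ratio of 0.998 (0.807 to 1.23), with 15.1, 6.48 and 5.49 CPM in the miR-211 libraries and 14.3, 5.91 and 6.03 in the controls of the same numbers. Other small nuclear RNA genes summed to 167.1 ± 82.0 CPM with U1 siRNA and 133.4 ± 8.28 with the scrambled oligo (exact permutation p 1), with 261.8 CPM in U1 siRNA replicate 2.

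No gene passed the threshold with U1 siRNA. Of the 12413 genes tested, 0 were higher and 0 lower by edgeR, DESeq2 or limma-voom, and 196 (1.58%) had an unadjusted p under 0.05 by edgeR, 77 by DESeq2 and 180 by limma-voom. On simulated counts of this comparison, 68.5% of genes changed by 2-fold were called and 38.0% of those changed by 1.5-fold. Here too 200 independent genes changed at once, so the shares can lie above those for a few changed genes. Without U1 siRNA replicate 2 there were also 0, with 384 at an unadjusted p under 0.05. Groups did not overlap in 6.27% of genes, where chance gives 10%. Of 7513 genes with a mean CPM of at least 10, 99.8% had a log2 fold change within 0.5 of 0.

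The genes named by the rule did not pass with U1 siRNA (adjusted p 0.9999 for each, edgeR). Among the highest by signed p were DNAJB6, a chaperone, with 178.3 ± 11.7 CPM against 143.5 ± 4.75 (log2 fold change 0.31, SE 0.08), PGAM1, a glycolytic enzyme (0.35, SE 0.09), NPIPB5 (0.73) and ITPK1, an inositol kinase (0.93). NPIPB5 belongs to a family of near-identical copies, so its count is uncertain. The lowest were GPBP1L1 (-0.27), CCNB1IP1 (-0.27), FZD6, a Wnt receptor (-0.33), SYNJ2BP (-0.29) and EDEM3, which acts in the degradation of misfolded proteins (-0.36). SNRNP70, SNRPA and SNRPC had log2 fold changes of 0.002, -0.05 and 0.02, and DROSHA, DGCR8, DICER1 and XPO5 had 0.02, 0.03, -0.07 and 0.02. MIR211 had 17 and 11 counts and TRPM1 30 and 24 in U1 siRNA and scrambled oligo libraries, 24 of the TRPM1 counts being in U1 siRNA replicate 2.

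Ribosomal protein genes were again the only list past the threshold, here downward: 14 of 83 were higher in value, with a median log2 fold change of -0.04 (camera, adjusted p 0.0108), and 0 members were called over all genes or adjusted over the list alone. The adjusted p was 0.863 with an estimated correlation. Without U1 siRNA replicate 2 the median was 0.001 (adjusted p 0.704), and without scrambled oligo replicate 1 it was -0.02 (0.633). With the share of pairs outside genes as a covariate, chosen after the data were seen, it was -0.02 (0.990). Adjusted over the list alone, 1 heat shock gene (DNAJB6) and 1 gene of hypoxia and glycolysis (PGAM1) were called. Members higher in value numbered 6 of 16 for the U1 snRNP and partners, 10 of 21 for Sm core and assembly, 8 of 18 for the U2 snRNP, 10 of 23 for the tri-snRNP, 5 of 22 for SR proteins, 7 of 27 for hnRNP proteins and 11 of 22 for cleavage and polyadenylation. They numbered 10 of 19 for nonsense-mediated decay, 9 of 23 for microRNA biogenesis, 25 of 44 for literature targets of miR-211, 12 of 23 for histones, 13 of 20 for interferon-stimulated genes, 1 of 3 for the inflammatory response and 7 of 14 for immediate early genes. They numbered 11 of 20 for p53 targets, 13 of 30 for the unfolded protein response, 5 of 16 for heat shock, 14 of 23 for cholesterol synthesis, 13 of 36 for mitosis, 15 of 36 for DNA replication and 16 of 24 for hypoxia and glycolysis. They numbered 4 of 4 for melanocyte genes, 4 of 5 for fibroblast markers, 3 of 16 for mitochondrially encoded genes and 2 of 3 for U1 snRNA genes. None of these lists passed (adjusted p 0.277 to 0.970). The U2 snRNP, tri-snRNP, SR protein, hnRNP, heat shock, mitosis and DNA replication lists passed without U1 siRNA replicate 3. The hnRNP, immediate early, unfolded protein response, mitosis and blood cell lists passed without U1 siRNA replicate 1. With an estimated correlation over all 6 libraries no list passed (adjusted p 0.863 to 0.971).

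Host genes of intronic microRNAs (475) had a median log2 fold change of 0.03 with U1 siRNA, against 0.01 for other genes (p 0.241, adjusted p 0.402), a difference of 0.02 that ran from -0.02 without U1 siRNA replicate 2 to 0.06 without U1 siRNA replicate 3. The longest 10% of genes (1078) had 0.07 against 0.007 (p 0.0299, adjusted p 0.0748, and 0.834 with an estimated correlation). This difference turned to -0.07 (adjusted p 3.00e-05) without U1 siRNA replicate 2, the library with 44.5% of pairs outside genes. It was 0.14 without U1 siRNA replicate 1, 0.16 without U1 siRNA replicate 3 and 0.10 without scrambled oligo replicate 2, each past the threshold, and -0.01 with the share of pairs outside genes as a covariate (adjusted p 0.713). Single-exon genes (142) differed by -0.04 (p 0.028, adjusted p 0.0748).

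**Figure D4:**
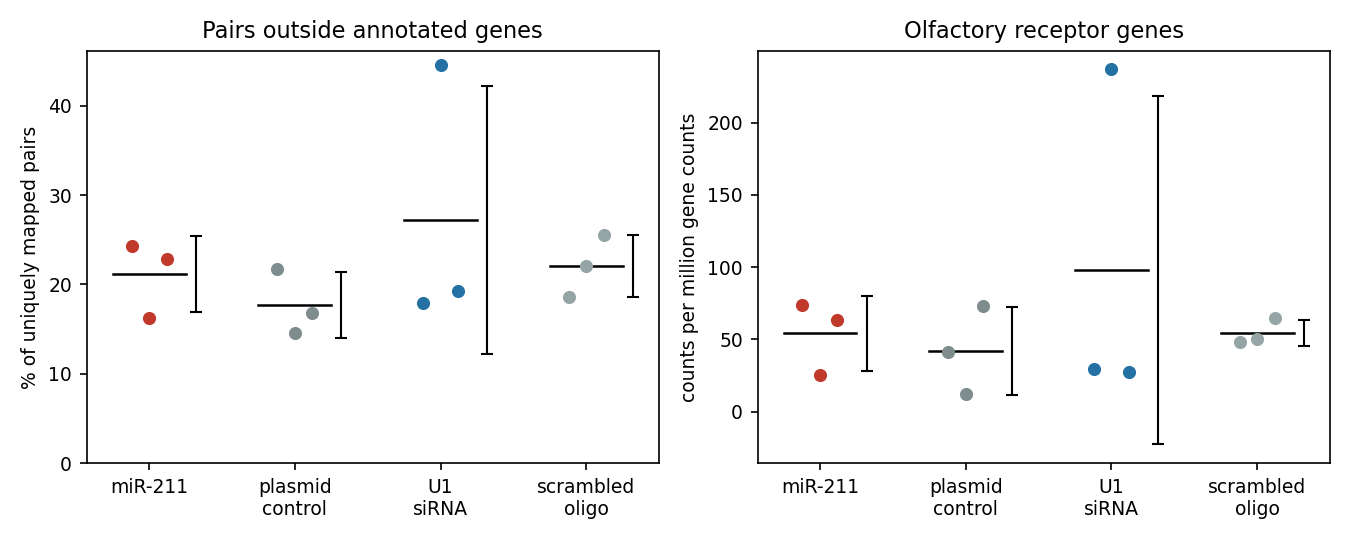
Share of uniquely mapped pairs outside annotated exons (%), per library, with pairs in introns counted as outside. The other panel gives CPM without scaling factors summed over 383 olfactory receptor genes that failed the expression filter. Points are libraries, horizontal lines group means and bars SD (n = 3). U1 siRNA replicate 2 lies at 44.5% and 236.7 CPM, above the other 11 libraries.

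The difference between both effects was tested over 13520 genes. MIR211 was the only call, with a log2 difference of 7.83 (SE 1.15, adjusted p 0.0447), and 234 genes had an unadjusted p under 0.05. DESeq2 also called 1 gene, and with the replicate block edgeR called 0, with 354 at an unadjusted p under 0.05. MIR211 was called without plasmid control replicate 2, without U1 siRNA replicate 2 and without scrambled oligo replicate 3, and the call was lost when any of the other 9 libraries was left out. Over the 12177 genes tested in both comparisons, the log2 fold changes had a Pearson r of 0.154 and a Spearman rho of 0.155, across genes, which are not independent replicates. The sign was the same in 57.3% of genes. No gene was called in both comparisons. When libraries were regrouped within each experiment, 45 of 100 groupings, the real grouping included, gave an absolute r as large. Without U1 siRNA replicate 2, r was -0.075.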

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

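The tests on olfactory receptor genes, on the other 2 U1 siRNA libraries and on DNM3 were chosen only after their results had been seen.

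The MIR211 effect differed between the experiments, with a log2 difference of 7.83 by the interaction test. That call was lost with the replicate block and in most fits with a library left out. The plasmid was given in only 1 of both experiments. Of the 100 regroupings, 16 called as many genes, the real one included, and the highest of the others called 384, so for the count of calls alone chance is not excluded. The count does not bear on MIR211 itself: 8 of the 16 keep the real grouping of the miR-211 experiment, and MIR211 had 244 to 273.4 CPM in the miR-211 libraries against at most 1.33 in the other 9. The rest of the 16, the highest included, used miR-211 splits that kept libraries of the same number together. In these interaction fits, no miR-211 split that parts all pairs, apart from the real grouping, called a gene. A regrouping with 384 calls points to a structure of the libraries apart from treatment.

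In U1 siRNA replicate 2, 44.5% of uniquely mapped pairs lay outside annotated exons, above the 18.6% to 25.5% of the scrambled oligo libraries. An effect of the siRNA on all 3 libraries was argued against, since the higher of the other 2 U1 siRNA libraries lay 2.78 percentage points below the scrambled oligo mean (-2.78). Unspliced RNA as the whole cause was argued against as well: short untested genes lying between genes had 2.87 times the CPM of the highest of the other 11 libraries. Reads from genomic DNA remain a candidate explanation. Olfactory receptor genes that failed the expression filter had, in this library, 3.20 times the CPM of the highest other library. Taste receptor, keratin-associated protein and defensin genes that failed it had 2.55 times. Failing the filter does not show that these genes are silent in these cells. An additional share of unspliced RNA in this library stays open, as short genes within tested genes were at 1.93 times.

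In strand column 3, which the comparisons did not use, MIR3120 had 142 counts over the 3 miR-211 libraries (49, 57 and 36) against 1 in the controls, a ratio of totals of 132 (23.3 to 5241). In strand column 4 it had 119 against 0. MIR3120 (chromosome 1, 172138808 to 172138888, GRCh38) overlaps MIR214 on the other strand, inside DNM3OS, so pairs there are ambiguous in the unstranded column. With 142 and 119 counts in the 2 strand columns, strand did not part these pairs. They therefore cannot be assigned to MIR3120 rather than MIR214. DNM3OS had 53 against 9 counts, a ratio of 5.46 (2.67 to 12.6), and an edgeR adjusted p of 0.350. These genes were chosen after their values were seen. Sequence shared with the MIR211 hairpin was argued against, the longest identical stretch being 9 bases. Higher transcription of DNM3, the gene around the locus, was argued against too, with a ratio of 0.757 (0.516 to 1.11). Counts of DNM3 do not bear on transcription of DNM3OS itself, which stays open. Whether the miR-211 plasmid carries sequence of this locus may be a candidate explanation that these files, without reads or the plasmid sequence, cannot test.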

How the results depend on the processing

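The covariate for pairs outside genes and the 14 U1 copies were added after seeing the data; the other alternatives were planned. MIR211 with the plasmid stayed past the threshold under every alternative run, its log2 fold change running from 8.38 to 10.6 when a library was left out. With miR-211, 2 genes were called without the low-count filter (AC010255.3 besides MIR211) and 2 with strand column 3 or 4 (MIR3120 besides MIR211); with U1 siRNA, 7 were called without the filter. MIR3120 had 0 counts in the unstranded column, where pairs over it are ambiguous with MIR214. The strand columns do not part the pairs of both genes either, so the MIR3120 call cannot be assigned to that gene. The cause of the added calls without the filter was not tested. Leaving out a library gave 1 to 1 call with miR-211 and 0 to 0 with U1 siRNA. Lists past the threshold with miR-211 were 0 with an estimated correlation, 2 with the covariate and 0 to 2 when a library was left out. With U1 siRNA they were 0 with an estimated correlation, 0 with the covariate and 0 to 8 when a library was left out, 8 without U1 siRNA replicate 3. The median of ribosomal protein genes with U1 siRNA ran from -0.0948 to 0.00148, the latter without U1 siRNA replicate 2.

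The difference of long genes with miR-211 passed with the strict filter (difference 0.039, adjusted p 0.0398), the replicate block (0.035, adjusted p 0.0413), the trend in expression and GC removed (0.035, adjusted p 0.0181) and both (0.037, adjusted p 0.0112). With the covariate for pairs outside genes, the difference changed sign and did not pass. With an estimated correlation its adjusted p was 0.712. Leaving out a library gave -0.00642 to 0.0857 with miR-211 and -0.074 to 0.157 with U1 siRNA, where the lowest value is that without U1 siRNA replicate 2; the cause was not tested. The replicate block gave 1 call with miR-211 and, besides the long genes and the interaction, changed no other call. Pairing by number was not shown for the U1 siRNA libraries (correlations 0.140, 0.091 and -0.048). Replicates 1 and 2 correlated best with their own number and replicate 3 did not, so the check cannot exclude pairing. The block by these numbers gave 0 calls. The interaction gave 0 calls with the replicate block and 0 to 1 when a library was left out. The correlation of effects ran from -0.075, without U1 siRNA replicate 2, to 0.243. The U1 snRNA target check was -30.3% over the 14 copies against -9.87%, and ran from -16.8% to -0.637% when a library was left out. The paired ratios (replicate block) gave -10.7%. Depth limits the U1 check, with 281 and 409 counts over the fixed list and 78 and 145 over the 14 copies. Most counts of the fixed list came from copies without the whole siRNA target.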

Other observations

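The tests with the covariate and the splits for genes called and for the correlation were chosen only after their results were seen.

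Ribosomal protein genes had medians of opposite sign in the 2 comparisons, 0.09 and -0.04, with adjusted p of 0.963 and 0.863 with an estimated correlation, and the latter median was 0.001 without U1 siRNA replicate 2. Their mean log2 CPM minus that of the other tested genes was 5.54, 5.70 and 5.63 with miR-211. Each lay above the control of the same number (5.47, 5.61 and 5.60). With miR-211 the share of pairs outside genes was argued against as the cause, since the median was 0.139 with it as a covariate, while a trend with expression, transcript length and GC content may account for part, as removing it left 0.040. With U1 siRNA the median was -0.018 with the covariate and -0.018 after removing the trend, so both remain candidate explanations. Treatment stays open as untested.

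With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. With miR-211, 5 splits called as many genes as the real 1, the highest other 13. The 3 other splits that part all pairs called 0, 0 and 1, while splits that part 1 pair and keep the others together called up to 13. For lists, 7 splits had as many past the threshold as the real 1, the highest other 6. For the 8mer genes, 7 splits gave as small a p, the smallest other 0.0152. For host genes 7 did, the smallest other 0.0437. For long genes 5 did, the smallest other 6.46e-09. Among the splits that part all pairs, the real p of 0.0195 for long genes was the smallest (others 0.107, 0.325 and 0.859), the lists past the threshold were 1 in the real split and 3, 0 and 0 in the others, and the smallest other p was 0.584 for the 8mer genes and 0.353 for host genes. Splits that part all pairs are fewer still than the 10, so being the smallest among them does not tell treatment from chance. With U1 siRNA the real split called 0 genes, so that all 10 splits had to call as many and the count tests nothing; the highest other called 187. That split set U1 siRNA replicate 2 and scrambled oligo replicates 1 and 2 against the rest, which points to a structure of the libraries apart from treatment. For lists 10 splits did, the highest other 12. For host genes 7 did, the smallest other 0.00989, and for long genes 10, the smallest other 2.51e-11. All 9 other splits thus gave a smaller p for long genes than the treatment did. For the correlation of both effects 45 of 100 did, the highest other absolute r being 0.416.

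MIR211 had 1 to 9 counts in each of the 9 libraries not given the miR-211 plasmid. In miR-211 replicate 3 the ratio of the strand columns' totals was 0.990, against 1.08 to 1.10 in the other 11 libraries.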
